A study of Homo sapiens with 18 samples.

How the data were processed

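Gene expression was measured on 18 Illumina bead arrays of the human multiple myeloma cell line KMS11. The labels describe 2 systems and 6 groups of 3 arrays. In the first system, a doxycycline-inducible short hairpin RNA aimed at the 5' region of MMSET (gene symbol NSD2, a histone methyltransferase) was left off (no DOX) or switched on (+DOX). In the second, cells labelled as MMSET knock-outs received a retrovirus that carried DSRed alone, MMSET II in its wild-type form, or MMSET II with the F1177A or the Y1118A change. The labels' design text says that 1 mutant is active and 1 catalytically inactive, and the labels name F1177A as the active and Y1118A as the inactive one. Samples were assigned to groups from their labels alone. The labels call the 3 arrays of a group triplicates and do not say that they came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

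RNA was amplified and labelled with biotin per the labels' protocols. The deposited table holds a probe intensity on a linear scale for each array, described as non-normalized per the file headers. Since 31.1% of the intensities lie below 0, a background had been subtracted before deposit, by a step not given in the sources used here. The deposited table also gives a detection p-value per probe and array, per the file headers. GenomeStudio 1.5.4 is named in the submitters' processing notes without a role. The authors' series matrix holds a second set of values for the same arrays, here read as intensity from its match to the deposited table. All its columns share 1 distribution (median 3 in each), so it was quantile-normalised across the arrays on the linear scale after background subtraction. The software step that did so is not given in the sources used here. It was used only as an alternative. All 54 per-sample columns were used.

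The table has 48803 probes. The platform annotation gave 1 gene symbol for 27578 of them, several for 13 and none for 21212, and 0 symbols changed when they were looked up by gene identifier. No gene was named from a probe with several symbols. Background was corrected with the neqc method of limma 3.58.1 in R 4.3.3, a normexp convolution whose negative-control mean and spread were inferred from the detection p-values, with an offset of 16. Values were quantile-normalised over all 18 arrays and put on the log2 scale. Because of the offset, log2 differences understate the change of dim genes. Probes were kept where the detection p-value was under 0.01 on at least 3 arrays, which left 13336. For each symbol the probe with the highest mean over all arrays was taken, and probes without a single symbol were kept as they were, giving 10954 features, of which 8947 were named genes and 2007 unnamed probes.

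Each comparison came from 1 limma model over all 18 arrays with a coefficient per group (12 residual degrees of freedom) and moderated variances with an intensity trend. Tests were two-sided, with Benjamini-Hochberg adjustment within each of the 7 comparisons. A feature was called changed at an adjusted p under 0.05. Errors given with log2 differences are standard errors (SE) of the model, and errors given with group levels are standard deviations (SD, n = 3). Where 1 of the 2 groups is near background, with the probe detected on none of its arrays or with a group mean under the mean of its arrays' lowest detected signals, the difference is given as at least N-fold, the mean of the brighter group against the mean, per array, of the higher of the lowest detected signal and the dim probe's own value. Gene lists were tested with camera, which compares a list with all other features, at a preset inter-gene correlation of 0.01 and again with the correlation estimated by statmod 1.5.0. Their p-values were adjusted over the lists of a comparison. Of 31 lists written from general knowledge, 27 had at least 5 measured members and 4 were not tested. Members called were counted over all genes and again adjusted over the list alone. On simulated data with 200 changed genes of 10954 in the +DOX against no DOX comparison, the procedure recovered 62.7% of genes changed 1.5-fold, 94% of those changed 2-fold and 98.5% of those changed 3-fold, and 6.59% of the called genes had not been changed. The simulated noise was independent, with 1 spread per feature in all groups and no brightness effect. These shares therefore check the procedure and do not give the error of the real comparison.

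Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The named genes are MMSET and its neighbours FGFR3, LETM1, TACC3, SLBP and NELFA, then the called genes with the largest rises and falls whose arrays do not overlap (8 each way for +DOX against no DOX and for MMSET II against DSRed, 5 each way elsewhere, without placeholder symbols), the 8 genes per direction with the largest opposite changes in the knock-down and MMSET II repletion, and up to 4 members per gene list, called ones first by size. Fewer list members are printed where a paragraph would grow long, taken from the top of the ranking and for called lists, and 1 gene of the opposite changes is not reported here. The alternatives were another offset without control information, no background correction, median scaling, cyclic loess, quantile normalisation within each system, the series matrix values, other detection filters, every probe, only the compared groups, a replicate block, array weights, no variance trend, stricter thresholds, an estimated correlation and leaving out each array. Median scaling used the median over all 48803 probes of an array, most of them not detected, so differences in brightness stay in the tested features. Array brightness as a covariate, a paired fit of the F1177A and MMSET II arrays, the set of genes shared by both active constructs, the alternatives for the overlap of the knock-down with F1177A and Y1118A, and the background limit on group means were chosen after seeing the data.

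Same-numbered arrays of F1177A and MMSET II deviated together from their group means (correlations 0.27, 0.17 and 0.22 across genes, and 6 of 6 arrays matched their own number best). The numbers, which come from the labels, may thus pair these arrays. The labels do not say what a number means, and pairing was not tested against chance. Replicate 1 was the brightest array of both groups, so brightness may also give this match. The values reported for this comparison come from the model without pairs, fixed beforehand, and the fits with the number as a block are alternatives. The files give no slide or scan date, so no batch could be tested. With 3 arrays against 3 the smallest two-sided exact permutation p is 0.1. Detected probes per array ranged from 10731 to 12170, and 3 arrays per group limit the precision of each value. Within a group arrays correlated at 0.9748 to 0.9976, between groups of 1 system at 0.9566 to 0.9862 and between systems at 0.8837 to 0.9133, and 0 pairs of arrays were identical.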

Results

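RNA levels of 10954 features were compared between 6 groups of 3 arrays of KMS11 cells, a multiple myeloma line that carries the t(4;14) translocation, which places MMSET and FGFR3 under immunoglobulin control. The knock-down arrays ask which genes move when MMSET is lowered, and the repletion arrays ask which genes move when wild-type, F1177A or Y1118A MMSET II is put back into cells labelled MMSET knock-outs, which otherwise received DSRed. Arrays differed in brightness. The 95th percentile of intensity was 349.4, 310.4 and 241.5 on the no DOX arrays, 620.7, 468.6 and 430.3 with +DOX, 491.4, 453.5 and 1033 with DSRed, 889.5, 775.6 and 621.9 with MMSET II, 493.1, 368.5 and 380 with F1177A, and 765.7, 746.5 and 775 with Y1118A.

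MMSET RNA was lower in the hairpin cells with doxycycline. Of 4 NSD2 probes, 3 were detected on no array. The remaining probe read 6.64 ± 0.15 (log2, SD, n = 3) without doxycycline and 5.94 ± 0.06 with it, a log2 difference of -0.70 (SE 0.132, limma adjusted p = 0.000369), or 1.62-fold lower. Under median scaling, where the median of all features with +DOX lay at 0.486, the NSD2 difference was -0.16 and no longer called (adjusted p = 0.515), and it lay at -0.642 relative to that median. In the repletion cells the same probe read 5.66 ± 0.03 with DSRed, 5.63 ± 0.19 with MMSET II, 5.77 ± 0.15 with F1177A and 5.80 ± 0.21 with Y1118A, with no called difference from DSRed (adjusted p = 0.887, 0.588 and 0.464). It was detected on 3 of 3 arrays in every group, DSRed included, so RNA at this probe is still seen in the cells labelled knock-outs. Whether this probe lies inside the retroviral constructs is not given in the sources used here, so it does not check the repletion labels. It was also dim in these cells, with intensities of 23.2 to 58.6, where the offset understates differences, so a modest rise could be missed. Among the neighbours of NSD2 on chromosome 4, the receptor kinase FGFR3 fell by 0.39 with +DOX (SE 0.0686, adjusted p = 0.000204). Under median scaling it was 0.0087, or -0.477 relative to all features, with no call (adjusted p = 0.959). The FGFR3 probe was very bright (14.43 with F1177A and 14.27 with Y1118A). Under median scaling its differences stayed between -0.088 and 0.0087 in all 7 comparisons, while the median of all features moved. Whether its called changes come from the normalisation was not tested. TACC3, a mitotic spindle protein, rose by 0.75 (adjusted p = 0.0095), with no call in a model of the compared groups alone (adjusted p = 0.0916). The histone mRNA binding protein SLBP rose by 0.47 (adjusted p = 0.023), with no call without no DOX replicate 1 (0.23) or without +DOX replicate 1 (0.40). LETM1 (adjusted p = 0.114) and NELFA (adjusted p = 0.452) were near background and not called. In the repletion cells none of these 5 neighbours was called against DSRed except FGFR3 with F1177A (0.29, adjusted p = 0.00574), which under median scaling was -0.08, or 0.332 relative to all features, with no call (adjusted p = 0.607).

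**Figure D1:**
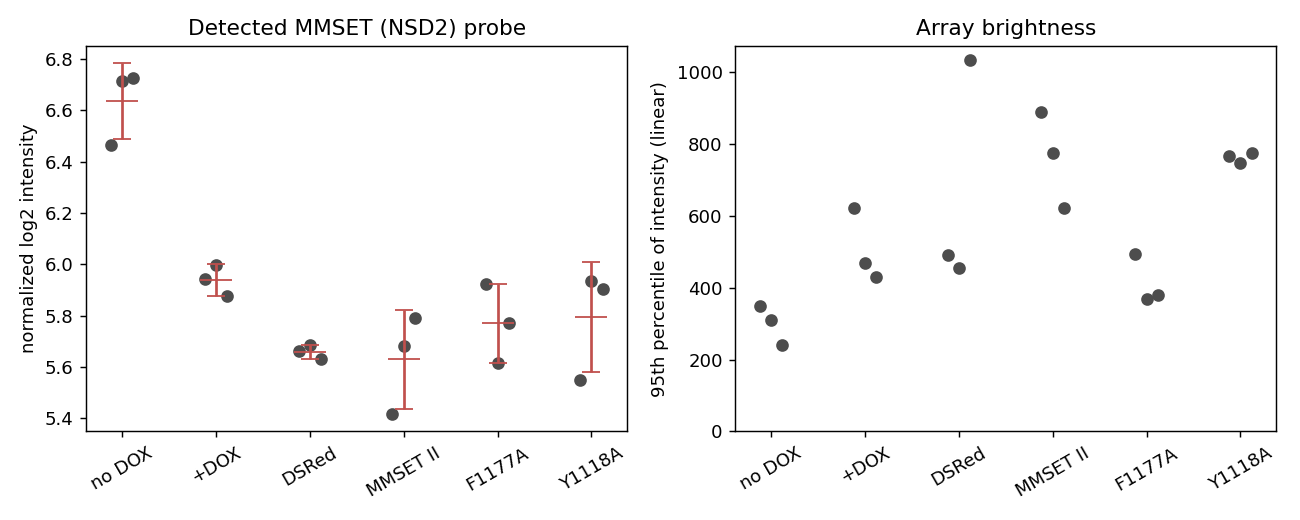
Left, level of the detected NSD2 probe (log2) on each array by group, with bars for mean ± SD (n = 3); right, the 95th percentile of intensity of each array. The NSD2 level is 6.64 without and 5.94 with doxycycline under quantile normalisation and lies between 5.63 and 5.80 in the repletion groups, and under median scaling the doxycycline difference is not called.

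With doxycycline the hairpin cells changed many genes, and none of the 4 gene lists called kept its call with an estimated correlation. INSIG1, the membrane protein that holds back the sterol-sensing transcription factors, rose (2.28, log2 difference, SE 0.146). PDIA4, a disulfide isomerase of the endoplasmic reticulum, fell (-1.83, SE 0.222). The largest rise was in CRIP2, a LIM-domain protein (3.57, SE 0.208), and the largest fall in RAB37, a small GTPase of exocytosis (-2.72, SE 0.118). In all, 4526 of 10954 features changed (2320 higher, 2206 lower; limma, adjusted p under the threshold), 463 of them at least 2-fold (218 higher, 245 lower). The 3 arrays of each group did not overlap for 44.2% of features, where chance gives 10%. Other large rises were FAM53A (2.47, with 0.97 at its other probe), COL18A1, the collagen chain that yields endostatin (2.32), and the hair keratin-associated gene KRTAP9-4 (2.23). FAM53A is also in the list of MMSET neighbours and relatives. SHISAL1, MAFA-AS1 and HDGFL3 were detected only with doxycycline and were at least 6.33-fold, 3.42-fold and 3.1-fold higher. Large falls were DENND6B (-2.54), the secretion protein SYTL1 (-2.31), the cholesterol-esterifying enzyme SOAT2 (-2.22), IGFBP6, which binds insulin-like growth factors (-1.99), and the Wnt receptor FZD2 (-1.92). The acyl-CoA synthetase ACSM3 was at least 3.56-fold lower, and the ADP-ribose hydrolase MACROD1 was at least 2.74-fold lower and not detected with doxycycline. Adjusted p-values of these 16 genes ran from 1.88e-11 to 3.46e-05.

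Of 27 lists tested, 4 were called with +DOX at the preset correlation and 0 of them kept the call with an estimated one. Of 16 measured sterol synthesis genes 14 rose (14 adjusted over the list alone), with a median of 1.00 (adjusted p = 6.08e-10, and adjusted p = 0.367 with an estimated correlation). The sterol cyclase LSS rose by 2.03, with 0.37 and 0.87 at its other probes, HMGCS1 of the mevalonate pathway by 1.87 and the epoxidase SQLE by 1.74. Of 19 unfolded protein response and chaperone genes 11 fell (11 adjusted over the list alone), with a median of -0.46 (adjusted p = 0.0081, and adjusted p = 0.855 with an estimated correlation), which turned to 0.08 under median scaling where it lay at -0.411 relative to the median of all features and was still called. The list call ended without no DOX replicate 1 (adjusted p = 0.382) or with array weights (-0.32, adjusted p = 0.122). WFS1, a membrane protein of the endoplasmic reticulum, fell by 1.04 but not under median scaling. Of 19 histone genes 8 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.33, adjusted p = 0.0138, and adjusted p = 0.552 with an estimated correlation), with H2AJ at 1.46, H1-2 at 1.29 and H2BC21 at 1.12. No call of the list remained with detection on all 18 arrays (adjusted p = 0.055). Of 24 nuclear-coded respiratory chain genes 11 rose (11 higher and 1 lower adjusted over the list alone; median 0.17, adjusted p = 0.0387, and adjusted p = 0.552 with an estimated correlation), among them COX7B (0.72), ATP5PO (0.55) and NDUFB3 (0.52). This list was not called without no DOX replicate 1 (adjusted p = 0.352), +DOX replicate 1 (0.066) or +DOX replicate 2 (0.0649). It also had no call with cyclic loess (0.0879), detection on all 3 arrays of a group (0.0627) or on all 18 arrays (0.055), or array weights (0.125). With median scaling the median of all features was 0.486, and this made 95.9% of calls higher, against 51.3%, and a model of the compared groups alone called 2828 features. The +DOX arrays were brighter by 0.752 (log2 of the 95th percentile).

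**Figure D2:**
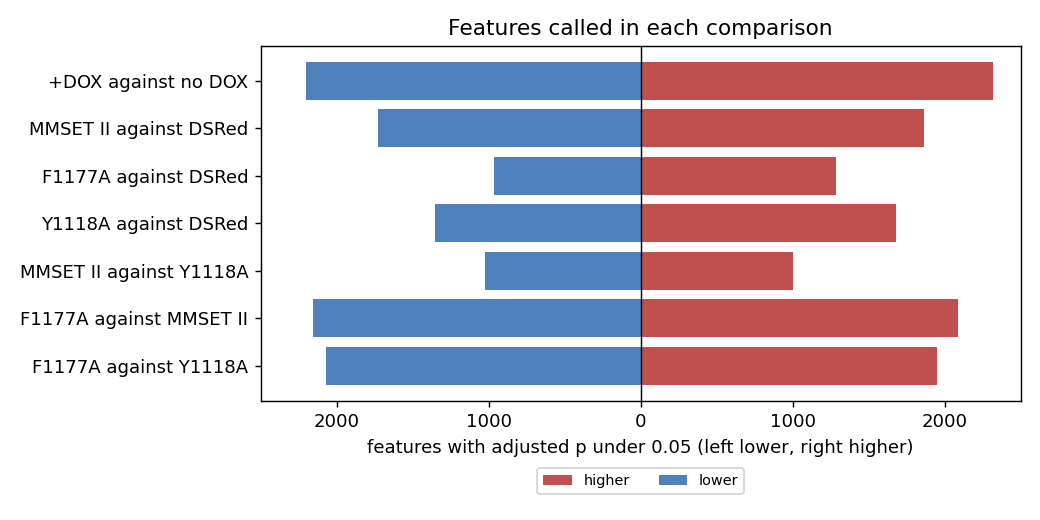
Number of features called (adjusted p under 0.05, limma, 3 arrays per group) in each comparison, higher to the right and lower to the left. Under quantile normalisation +DOX against no DOX has the most calls, 4526, and MMSET II against Y1118A the fewest, 2025. The share called higher lies between 48.5% and 57.2%, though of changes of at least 2-fold with F1177A against DSRed 218 are higher and 36 lower. Under median scaling, which leaves brightness differences in, the share called higher is 95.9% with +DOX and 2.63% for F1177A against MMSET II.

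Against DSRed, wild-type MMSET II came with higher levels of genes reported high in t(4;14) myeloma and of ERK feedback and target genes, and with lower levels of histone and plasma cell genes. These 4 lists kept their call with an estimated correlation. At the preset correlation Y1118A was called the same way for each of them against the same DSRed arrays, and F1177A for all but the ERK list. The plasma cell list was not called in MMSET II against Y1118A. Whether the shared DSRed arrays give these list calls was not tested. The annexin partner S100A10 rose by 4.08 (SE 0.187, adjusted p = 7.75e-12) and N-cadherin, CDH2, by 2.85 (SE 0.158, adjusted p = 7.55e-11). The largest fall was in GCHFR, which regulates tetrahydrobiopterin synthesis (-2.75, SE 0.161, adjusted p = 1.65e-10). The noncoding RNA SNAR-A1 rose by 3.50, though near-identical copies share its sequence, and the ISG15 ligase HERC5 by 2.71. The glycosyltransferase GALNT18, carbonic anhydrase CA2, actin-associated RAI14 and collagen lysyl hydroxylase PLOD2 were not detected with DSRed and were at least 4.85-fold, 4.07-fold, 3.9-fold and 3.45-fold higher. Falls followed in YPEL3 (-2.09), the calcium-channel regulator CRACR2B (-2.08), the PI3K inhibitor PIK3IP1 (4.01-fold lower), TMEM140 (-1.87), the peptide hormone ADM (-1.86), the urea-cycle enzyme ASS1 (-1.84) and butyrylcholinesterase, BCHE (-1.73). In all, 3594 features changed (1865 higher, 1729 lower), 409 at least 2-fold (293 higher, 116 lower). Groups did not overlap for 44.3% of features, against 10% by chance.

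For MMSET II against DSRed 11 lists were called, and 5 kept the call with an estimated correlation. Of 12 genes reported high in t(4;14) myeloma 7 rose (7 adjusted over the list alone; median 0.49, adjusted p = 0.000633, and adjusted p = 0.0273 with an estimated correlation), including the protease inhibitor SERPINE2 (1.96), the junction protein JAM3 (1.59) and KLF4 (at least 1.03-fold). Of 14 ERK feedback and target genes 7 rose (7 adjusted over the list alone; median 0.42, adjusted p = 0.000751, estimated 0.0273), with ETV4 at least 2.5-fold higher, the phosphatase DUSP5 at 1.48 and ETV5 at 0.94. The cyclin CCND2 is a member of both this list and the t(4;14) list. Of 27 histone-modifier genes 11 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.21, adjusted p = 0.00936, estimated 0.0392), among them the Polycomb genes CBX2 (1.52) and BMI1 (0.73) and the methyltransferase SMYD3 (1.41). Under median scaling this list was not called (adjusted p = 0.108), with a median of 0.43, 0.214 above that of all features. Of 19 histone genes 13 fell and 2 rose (16 and 2 adjusted over the list alone; median -0.76, adjusted p = 4.1e-05, estimated 0.0449), with H2AC6 at -1.47 and H4C8 at -1.35. Of 18 plasma cell genes 8 fell (8 lower and 1 higher adjusted over the list alone; median -0.26, adjusted p = 0.00472, estimated 0.0363). The plasma cell surface proteoglycan SDC1 was at least 2.17-fold lower, and the secretory genes MZB1 and FKBP11 fell by 1.27 and 1.05.

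The other 6 lists lost the call with an estimated correlation. Of 26 G1/S genes 22 rose (24 adjusted over the list alone; median 0.55, adjusted p = 1.91e-08, and adjusted p = 0.247 with an estimated correlation), with CCNE1, the cyclin of S-phase entry, at 1.43, UHRF1 at 1.31 and the replication gene GINS2 at 1.22. Of 27 MYC and ribosome biogenesis genes 9 rose (9 adjusted over the list alone; median 0.26, adjusted p = 0.00936, and adjusted p = 0.195 with an estimated correlation), led by NOP56 (0.89). Of 23 ATF4-response genes 12 fell (13 adjusted over the list alone; median -0.42, adjusted p = 0.000294, and adjusted p = 0.393 with an estimated correlation), led by the stress transcription factor DDIT3 (-1.57). Of 19 unfolded protein response genes 6 fell (6 adjusted over the list alone; median -0.38, adjusted p = 0.00656, and adjusted p = 0.504 with an estimated correlation), with DNAJB9 at -1.08 and EDEM1 at -0.99. The G1/S, ATF4-response, unfolded protein response and histone-modifier lists were called the same way with F1177A and Y1118A against DSRed. None of them was called in MMSET II against Y1118A, so these calls are not particular to MMSET II. Of 7 epithelial-mesenchymal genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.23, adjusted p = 0.0171, and adjusted p = 0.0706 with an estimated correlation), namely mesenchymal CDH2, TWIST1 (0.74) and the epithelial EPCAM, at least 3.1-fold higher. Of 26 mitochondrial ribosome genes 5 rose (1 adjusted over the list alone; median 0.21, adjusted p = 0.0486, and adjusted p = 0.318 with an estimated correlation), led by MRPL11 (0.54). The call of this list was lost without DSRed replicate 1 (0.113), DSRed replicate 2 (0.103), MMSET II replicate 1 (0.11) or MMSET II replicate 2 (0.0515), or under median scaling (0.138, with a median of 0.45, 0.236 above that of all features). It also had no call with cyclic loess, quantile normalisation within each system, the series matrix values, detection on all 3 arrays of a group, a replicate block or brightness as a covariate (adjusted p from 0.0502 to 0.0726). Median scaling moved the median of all features to 0.212, called 1443 features with 84.8% higher, against 51.9%, and ended the calls of DDIT3, DNAJB9 and EDEM1. The MMSET II arrays were brighter than the DSRed arrays by 0.3.

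F1177A, labelled active, changed 2250 features against DSRed (1287 higher, 963 lower), 254 at least 2-fold (218 higher, 36 lower). S100A10 rose by 3.67 (SE 0.187, adjusted p = 3.24e-11) and TMSB15A, an actin-binding thymosin with a near-identical copy, by 2.99 (SE 0.153, adjusted p = 3.24e-11). CA2, PLOD2 and GALNT18 were not detected with DSRed and were at least 4.35-fold, 3.97-fold and 4.3-fold higher. CBLN2, a secreted synaptic protein, was at least 3.86-fold lower (adjusted p = 1.7e-08), and the globin HBD, which has near-identical relatives, fell by 1.61. ADM, LAMP5 and GALNT13 were at least 3.58-fold, 2.19-fold and 2.06-fold lower. Groups did not overlap for 37.6% of features, against 10% by chance.

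For F1177A against DSRed 13 lists were called, 6 of which kept the call with an estimated correlation. Of 12 genes reported high in t(4;14) myeloma 4 rose (5 adjusted over the list alone; median 0.29, adjusted p = 0.000184, estimated 0.0192), led by SERPINE2 and by CDH2 (1.89), though the list median turned to -0.09 under median scaling, 0.325 above that of all features. Of 21 matrix and cytoskeleton genes 7 rose (8 adjusted over the list alone; median 0.20, adjusted p = 0.000158, estimated 0.0171), with the focal adhesion genes ZYX at 1.04 and VCL at 0.79, and this median turned to -0.02 under median scaling, 0.393 above that of all features. Of 6 markers of fibroblasts, endothelium and epithelium, written as a check for other cell types, 3 rose (3 adjusted over the list alone; median 0.51, adjusted p = 0.00446, estimated 0.0341), with EPCAM at least 1.86-fold higher, PDGFRB at least 1.74-fold higher and ACTA2 at 0.81. Of 27 histone-modifier genes 7 rose (8 adjusted over the list alone; median 0.23, adjusted p = 0.0097, estimated 0.0341), led by KDM5B (0.68) and DNMT1 (0.56), but under median scaling the median turned to -0.21, 0.207 above that of all features, with no call (adjusted p = 0.277). Of 19 histone genes 12 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.63, adjusted p = 5.73e-06, estimated 0.0341), with H4C8 at -1.53 and H2BC5 at -1.07. Of 18 plasma cell genes 6 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.18, adjusted p = 0.00446, estimated 0.0341), with SDC1 at least 1.86-fold lower, the immunoglobulin joining chain JCHAIN at -1.10 and the transcription factor IRF4 at -0.55.

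The remaining 7 lists of F1177A against DSRed lost the call. Of 26 G1/S genes 18 rose (22 adjusted over the list alone; median 0.54, adjusted p = 1.59e-09, and adjusted p = 0.226 with an estimated correlation), with GINS2 at 0.99 and CDT1 at 0.89. Of 30 mitotic genes 6 rose (7 adjusted over the list alone; median 0.26, adjusted p = 0.00203, and adjusted p = 0.573 with an estimated correlation), and the median turned to -0.24 under median scaling, 0.172 above that of all features, with no call (adjusted p = 0.123). MKI67, the proliferation marker, rose by 0.67, with no call without DSRed replicate 3 (0.53, adjusted p = 0.0707) or without F1177A replicate 2 (0.53, adjusted p = 0.0848). Of 19 antigen presentation genes 6 rose (7 adjusted over the list alone; median 0.29, adjusted p = 0.000721, and adjusted p = 0.232 with an estimated correlation), led by HLA-DMB (1.14) and HLA-DMA (0.80). The median turned to -0.11 under median scaling, 0.307 above that of all features, with no call (adjusted p = 0.0659). Of 19 unfolded protein response genes 9 fell (12 adjusted over the list alone; median -0.65, adjusted p = 5.73e-06, and adjusted p = 0.347 with an estimated correlation), led by PDIA4 and the chaperone HYOU1 (-0.98, adjusted p = 0.0622 with array brightness as a covariate). Of 23 ATF4-response genes 9 fell (13 lower and 1 higher adjusted over the list alone; median -0.47, adjusted p = 5.35e-05, and adjusted p = 0.376 with an estimated correlation), led by the tryptophan tRNA synthetase WARS1 (-1.02). Of 26 mitochondrial ribosome genes 4 fell (4 adjusted over the list alone; median -0.15, adjusted p = 0.00633, and adjusted p = 0.228 with an estimated correlation), among them MRPL19 (-0.69), whose call ended with array brightness as a covariate. Of 7 epithelial-mesenchymal genes CDH2, EPCAM and TWIST1 (1.32) rose and the tight junction gene TJP1 fell by 0.70 (3 and 1 over all genes, 3 and 1 adjusted over the list alone). Their median, -0.01, and mean, 0.56, differ in sign, the test was upward (adjusted p = 0.0486, and adjusted p = 0.146 with an estimated correlation), and the median turned to 0.21 with cyclic loess. That call was lost without DSRed replicate 1 (0.0696), DSRed replicate 2 (0.0791) or F1177A replicate 2 (0.0505). It was also lost with another offset, cyclic loess, quantile normalisation within each system or a replicate block (adjusted p from 0.0512 to 0.0758). Median scaling moved the median of all features to -0.413 and left 18% of calls higher, against 57.2%, and ended the calls of ZYX, VCL, ACTA2, KDM5B, DNMT1, GINS2, CDT1, MKI67, HLA-DMB and HLA-DMA. The brightness difference was -0.579.

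Y1118A, labelled inactive, also came with many changed genes. TMSB15A rose by 2.73 (SE 0.153, adjusted p = 3.95e-10), HERC5 by 2.61 (SE 0.12, adjusted p = 1.85e-11) and the actin-linking kinase substrate MARCKS by 2.21 (SE 0.0981, adjusted p = 1.54e-11). MYOF, a membrane-repair protein, was not detected with DSRed and was at least 3.6-fold higher, and TMSB15B rose by 2.08, with 0.09 at 1 of its other probes. The heat-shock gene HSPA6 was at least 3.0-fold lower, and the aldolase ALDOC (-1.82), the inhibin subunit INHBE (-1.77), ASS1 (-1.68) and the exonuclease ISG20 (-1.57) fell. In all, 3038 features changed (1681 higher, 1357 lower), 187 at least 2-fold (119 higher, 68 lower). The count was 1901 without DSRed replicate 1, 1923 without DSRed replicate 2 and 2016 without Y1118A replicate 3. Groups did not overlap for 43.9% of features, against 10% by chance.

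For Y1118A against DSRed 13 lists were called, and 2 kept the call with an estimated correlation. Of 18 plasma cell genes 9 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.29, adjusted p = 0.000133, estimated 0.0176), with JCHAIN at -1.12 and FKBP11 at -1.09. Of 27 histone-modifier genes 11 rose (11 adjusted over the list alone; median 0.18, adjusted p = 0.00175, estimated 0.0267), with CBX2 at 1.25, SMYD3 at 0.95 and DNMT1 at 0.83. The calls of the other 11 lists were lost. Of 16 sterol synthesis genes 14 fell (15 adjusted over the list alone; median -0.68, adjusted p = 5.68e-09, and adjusted p = 0.0878 with an estimated correlation), with DHCR7 at -1.53 and the mevalonate kinase MVK at -0.99. Of 26 G1/S genes 19 rose (22 adjusted over the list alone; median 0.53, adjusted p = 5.68e-09, and adjusted p = 0.219 with an estimated correlation), with CCNE1 at 1.21, MCM10 at 0.94 and MCM3 at 0.92. Of 28 DNA repair genes 9 rose and 2 fell (9 and 2 adjusted over the list alone; median 0.23, adjusted p = 0.0233, and adjusted p = 0.0878 with an estimated correlation), with EXO1 at 0.94, though 0.22 at its other probe, and MSH6 at 0.84. The list call ended without DSRed replicate 3 (0.0595) or with array weights (0.0542). Of 30 mitotic genes 10 rose (11 adjusted over the list alone; median 0.33, adjusted p = 0.00166, and adjusted p = 0.491 with an estimated correlation), led by CENPF (0.80). Of 12 genes reported high in t(4;14) myeloma 5 rose (5 adjusted over the list alone; median 0.26, adjusted p = 0.00348, and adjusted p = 0.0572 with an estimated correlation), with SERPINE2 at 1.24 and CDH2 at 1.10. Of 7 epithelial-mesenchymal genes 3 rose (4 adjusted over the list alone; median 0.44, adjusted p = 0.0118, and adjusted p = 0.079 with an estimated correlation), namely CDH2, EPCAM and TWIST1. Of 14 ERK feedback and target genes 4 rose (4 adjusted over the list alone; median 0.18, adjusted p = 0.0474, and adjusted p = 0.125 with an estimated correlation), with ETV5 at 0.92 and the cyclin CCND3 at 0.60. No call of the list remained without DSRed replicate 1 (0.0507), DSRed replicate 3 (0.107), Y1118A replicate 2 (0.0527) or Y1118A replicate 3 (0.0645). It was also not called with detection on all 3 arrays of a group (0.101) or on all 18 arrays (0.0934), array weights (0.0819) or brightness as a covariate (0.0509).

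With Y1118A against DSRed, 13 of 23 ATF4-response genes fell (16 lower and 1 higher adjusted over the list alone; median -0.47, adjusted p = 1.6e-07, and adjusted p = 0.226 with an estimated correlation), with DDIT3 at -1.48 and the pseudokinase TRIB3 at -1.45. Of 19 unfolded protein response genes 7 fell (8 adjusted over the list alone; median -0.50, adjusted p = 5.66e-05, and adjusted p = 0.357 with an estimated correlation), with DNAJB9 at -1.22 and CREB3L2 at -1.19. Of 19 histone genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.38, adjusted p = 0.0211, and adjusted p = 0.22 with an estimated correlation), led by H4C8 (-1.13). This list was not called with detection on all 18 arrays (-0.16, adjusted p = 0.303), without background correction (adjusted p = 0.0878) or with brightness as a covariate (-0.27, adjusted p = 0.0509). Of 19 antigen presentation genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.15, adjusted p = 0.0423, and adjusted p = 0.393 with an estimated correlation), led by HLA-F (-0.95) and HLA-G (-0.89). The median turned to 0.12 under median scaling, where it lay below that of all features, with no call (0.0559). The call of this list was lost without DSRed replicate 1 (0.0833), DSRed replicate 2 (0.0546) or Y1118A replicate 3 (0.065). It was also not called with quantile normalisation within each system (0.0511) or with brightness as a covariate (median -0.07, adjusted p = 0.0674). Median scaling moved the median of all features to 0.214, called 831 with 88.2% higher, against 55.3%, and ended the calls of DDIT3, DNAJB9, H4C8 and HLA-G. The Y1118A arrays were brighter than the DSRed arrays by 0.315.

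Wild-type MMSET II and the form labelled inactive differed in 2025 features (1003 higher, 1022 lower), 169 at least 2-fold (121 higher, 48 lower). The chemokines CCL3L3 (3.63, SE 0.148, adjusted p = 2.74e-12) and CCL3 (at least 8.07-fold, adjusted p = 3.75e-11) were higher with MMSET II, and CCL3L1 at least 3.56-fold, though its other probe gave -0.01 and probes of this family share near-identical sequences. SNAR-A1 was higher by 3.48 and S100A10 by 2.24. MARCKS was lower by a log2 difference of -2.96 (SE 0.0981, adjusted p = 1.2e-13), ADM of -2.93 and GCHFR of -2.03, and the lysosomal membrane protein LAMP5 and the Wnt regulator KREMEN2 were at least 4.99-fold and 3.04-fold lower. The count was 1348 without Y1118A replicate 1. Groups did not overlap for 48.2% of features, against 10% by chance. Of the 7 lists called here 0 kept the call with an estimated correlation. Of 16 sterol synthesis genes 14 were higher (14 adjusted over the list alone; median 0.68, adjusted p = 1.19e-09, and adjusted p = 0.156 with an estimated correlation), with HMGCS1 at 1.43 and DHCR7 at 1.25. Of 27 MYC and ribosome biogenesis genes 10 were higher (13 higher and 1 lower adjusted over the list alone; median 0.33, adjusted p = 0.00024, and adjusted p = 0.156 with an estimated correlation), led by NOP16 (0.82, and 0.70 with no call without MMSET II replicate 3) and PES1 (at least 1.68-fold). Of 19 histone genes 6 were lower and 1 higher (7 and 1 adjusted over the list alone; median -0.27, adjusted p = 0.00834, and adjusted p = 0.174 with an estimated correlation), led by H2AC6 (-1.23). Of 30 mitotic genes 5 were lower (5 adjusted over the list alone; median -0.21, adjusted p = 0.0101, and adjusted p = 0.704 with an estimated correlation), led by KIF20A (-0.62). Of 23 glycolysis and hypoxia genes 8 were higher and 2 lower (10 and 2 adjusted over the list alone; median 0.23, adjusted p = 0.0246, and adjusted p = 0.172 with an estimated correlation), with the hexokinase HK1 at 1.26 against ADM. Of 12 genes reported high in t(4;14) myeloma 3 were higher (4 adjusted over the list alone; median 0.12, adjusted p = 0.042, and adjusted p = 0.156 with an estimated correlation), with CDH2 at 1.75 and JAM3 at 1.32. The list call ended without background correction (0.0545), with array weights (0.0625) or with brightness as a covariate (0.0574). Of 14 ERK feedback and target genes 3 were higher (3 adjusted over the list alone; median 0.11, adjusted p = 0.042, and adjusted p = 0.156 with an estimated correlation), with ETV4 at least 2.69-fold higher and DUSP5 at 1.45. No call of the list remained without MMSET II replicate 1 (0.0714), without background correction (0.1), with detection on all 18 arrays (0.06, adjusted p = 0.179), with array weights (0.0836) or with brightness as a covariate (0.0589). Median scaling called 561 features with 67.9% higher, against 49.5%, and ended the call of KIF20A, and a model of the compared groups alone called 4074.

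F1177A and wild-type MMSET II, both labelled active, differed in more features than MMSET II and Y1118A in the main model, though the latter count depended on the model. With F1177A the chemokine CCL3L3 was lower by a log2 difference of -3.89 (SE 0.148, adjusted p = 1.53e-12), CCL3 was at least 7.72-fold, MYOF at least 3.59-fold and CCL3L1 at least 3.39-fold lower, with -0.09 at the other CCL3L1 probe, and SNAR-A1 lay at -1.88. PIK3IP1 (2.58, SE 0.129, adjusted p = 4.62e-11), YPEL3 (2.50), MARCKS (2.39), TMEM140 (2.23) and GCHFR (2.22) were higher. In all, 4251 features differed (2091 higher, 2160 lower), 287 at least 2-fold (181 higher, 106 lower). Groups did not overlap for 58% of features, against 10% by chance. FGFR3 was higher by 0.30 (adjusted p = 0.0023), which under median scaling was -0.01, or 0.608 relative to all features, with no call (adjusted p = 0.937). The 4 lists called lost the call with an estimated correlation. Of 19 antigen presentation genes 13 were higher (15 adjusted over the list alone; median 0.43, adjusted p = 3.24e-05, and adjusted p = 0.213 with an estimated correlation), led by HLA-DQB1 (1.21) and HLA-DMA (1.04). The median turned to -0.23 under median scaling, 0.395 above that of all features. Of 27 MYC and ribosome biogenesis genes 18 were lower and 1 higher (18 and 1 adjusted over the list alone; median -0.41, adjusted p = 0.000775, and adjusted p = 0.14 with an estimated correlation), with the nucleolar protein NCL at -1.14 and the lactate dehydrogenase LDHA at -1.02. Of 26 mitochondrial ribosome genes 16 were lower (19 lower and 1 higher adjusted over the list alone; median -0.32, adjusted p = 0.000167, and adjusted p = 0.14 with an estimated correlation), with MRPL19 at -1.14 and GFM1 at -0.94. Of 14 ERK feedback and target genes 5 were lower (5 adjusted over the list alone; median -0.24, adjusted p = 0.045, and adjusted p = 0.14 with an estimated correlation), with MAFF at least 1.73-fold lower and ETV4 at -0.97. This list was not called without MMSET II replicate 3 (0.0862), without F1177A replicate 1 (0.0736) or under median scaling (0.146). It was also not called without background correction (0.168), with the series matrix values (0.055), with array weights (0.0894) or with detection on all 18 arrays (-0.13, adjusted p = 0.477). The brightness difference was -0.878, whereas it was -0.0154 for MMSET II against Y1118A. Array brightness as a covariate left 2537 calls, without NCL and LDHA. Median scaling moved the median of all features to -0.620, called 6543 with 2.63% higher, against 49.2%, and ended the calls of HLA-DQB1 and HLA-DMA.

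F1177A and Y1118A, which the labels set apart by catalytic activity, differed in 4020 features (1950 higher, 2070 lower), 269 at least 2-fold (174 higher, 95 lower). COL22A1 and HSPA6 were not detected with Y1118A and were at least 3.09-fold and 3.03-fold higher with F1177A. The RNA-binding protein IGF2BP2 (adjusted p = 4.37e-09) and CLYBL were at least 4.48-fold and 4.39-fold higher, and the acetyl-CoA synthetase ACSS2 was higher by 2.25. ADM, MYOF and LAMP5 were not detected with F1177A and were at least 7.51-fold, 3.79-fold and 4.62-fold lower, CBLN2 was at least 4.05-fold lower and the cell adhesion molecule NRCAM was lower as well (-2.13). Groups did not overlap for 61.3% of features, against 10% by chance. The 3 lists called lost the call with an estimated correlation. Of 16 sterol synthesis genes 14 were higher (14 adjusted over the list alone; median 0.79, adjusted p = 1.22e-07, and adjusted p = 0.238 with an estimated correlation), with HMGCS1 at 1.64 and DHCR7 at 1.48. Of 19 antigen presentation genes 13 were higher (14 adjusted over the list alone; median 0.56, adjusted p = 5.93e-06, and adjusted p = 0.238 with an estimated correlation), led by HLA-F (1.14) and HLA-DQB1 (1.01). The median turned to -0.11 under median scaling, 0.509 above that of all features. Of 26 mitochondrial ribosome genes 13 were lower and 2 higher (13 and 2 adjusted over the list alone; median -0.21, adjusted p = 0.0299, and adjusted p = 0.448 with an estimated correlation), led by MRPL3 (-0.81) and GFM1 (-0.66). The call of this list was lost without Y1118A replicate 3 (0.0594) or with brightness as a covariate (0.0524). The brightness difference was -0.894. Array brightness as a covariate left 1319 calls, without MRPL3 and GFM1. Median scaling moved the median of all features to -0.618, called 6831 with 3.91% higher, against 48.5%, and ended the calls of HLA-F and HLA-DQB1.

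**Figure D3:**
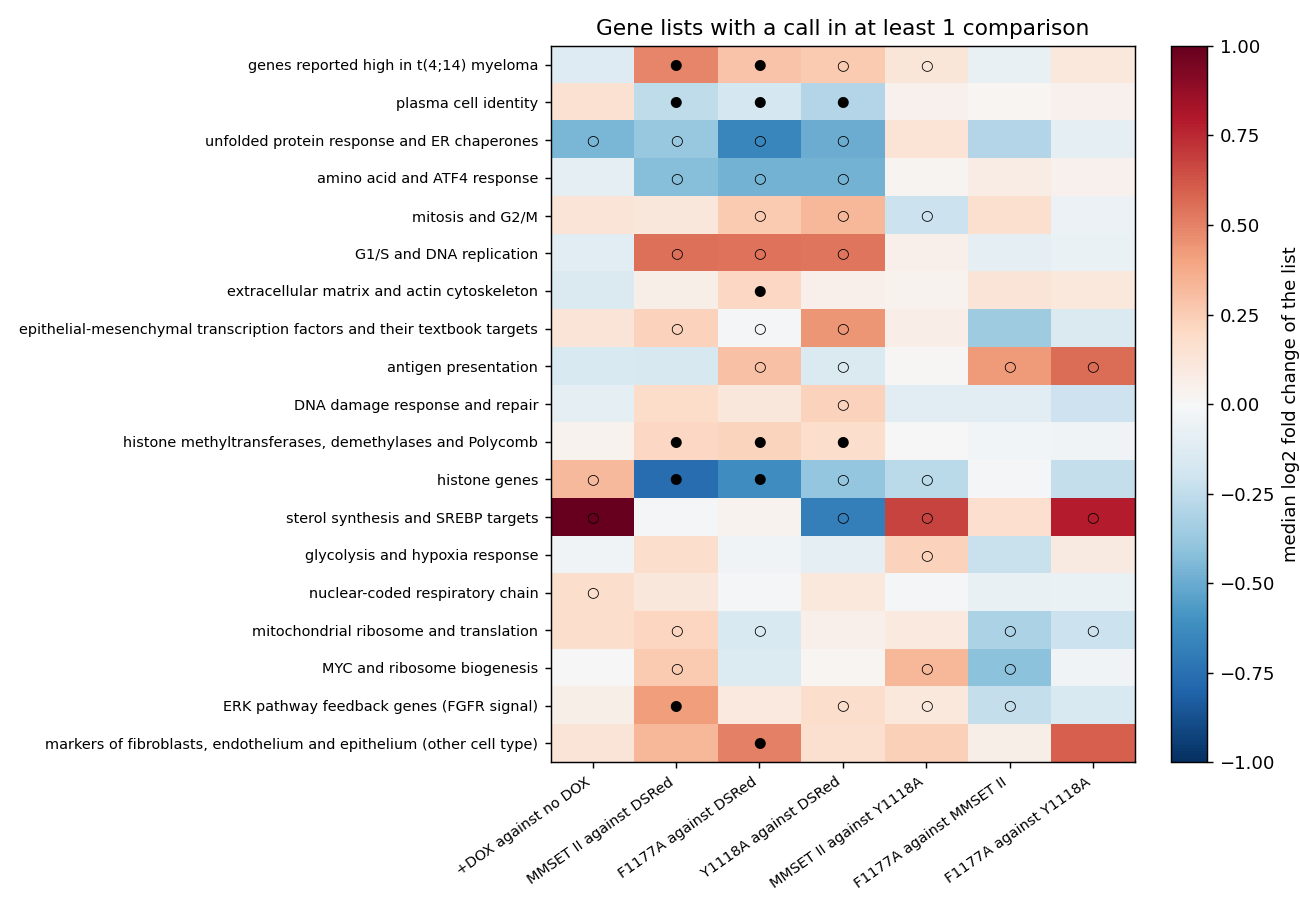
Median log2 difference of each gene list called in any comparison, on a colour scale from -1 to 1; filled dots are calls kept with an estimated correlation and open circles calls at the preset correlation only (camera, 3 arrays per group). Sterol genes have medians of 1.00 with +DOX and -0.68 with Y1118A against DSRed, and colours are from quantile normalisation, whereas under median scaling antigen presentation medians flip sign for every comparison in which that list was called, the unfolded protein response median flips with +DOX, and for F1177A against DSRed the t(4;14), matrix, histone-modifier and mitotic medians flip as well.

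Genes that answer to MMSET in both systems would move in opposite directions under knock-down and MMSET II repletion. Of the features tested, 539 did so (310 fell with +DOX and rose with MMSET II, 229 rose and then fell), below the 742 that independent lists of these sizes give, whereas 1138 moved the same way (578 fell in both, 560 rose in both), above 743. How these counts lay against independent lists depended on the setting. Under median scaling 105 moved oppositely and 498 the same way, near the 113 and 515 of independent lists. With no detection filter both counts exceeded independent lists, with 351 opposite (152) and 703 the same way (153), as they did for changes of at least 1.5-fold, with 150 (138) and 299 (138). Without DSRed replicate 3 they were 543 and 1773. Leaving out the filter adds undetected features, which lowers the numbers for independent lists. In each of these settings the opposite count stayed under the same-way one. Fisher's exact test gave an odds ratio of 0.22 (p = 3.18e-50) over genes, which are not independent. The matrix gene TSKU was at least 2.36-fold lower with +DOX (adjusted p = 9.2e-08) and at least 1.56-fold higher with MMSET II, and the phospholipase PLCG2 fell by 1.59 and was at least 2.9-fold higher. The transcription factor CEBPA was at least 2.46-fold lower and rose by 2.49, and the transcription factor IRX3 (-1.27 and 1.35) and the cyclin CCNE1 (-1.46 and 1.43) moved likewise. PNMA3 (which fell by 1.53) and LRP3 (at least 2.56-fold lower with +DOX) were at least 1.96-fold and 1.72-fold higher with MMSET II, and the interleukin receptor chain IL2RB was at least 2.19-fold lower and then at least 1.19-fold higher. In the other direction, ADM rose by 2.10 and fell by 1.86, TP53INP1 rose by 1.02 and fell by 1.59, H2AJ rose by 1.46 and fell by 0.85, and H2AC18 rose by 0.89 and fell by 0.91. NECTIN1 was at least 1.82-fold higher with +DOX and fell by 0.92 with MMSET II, FBXL16 was at least 1.17-fold higher and fell by 0.85, and CBLN2, near background in both knock-down groups, was called higher with +DOX and fell by 1.31 with MMSET II. Median scaling ended the falls of H2AC18 and FBXL16 with MMSET II, and cyclic loess ended the call of CBLN2 with +DOX (adjusted p = 0.161).

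**Figure D4:**
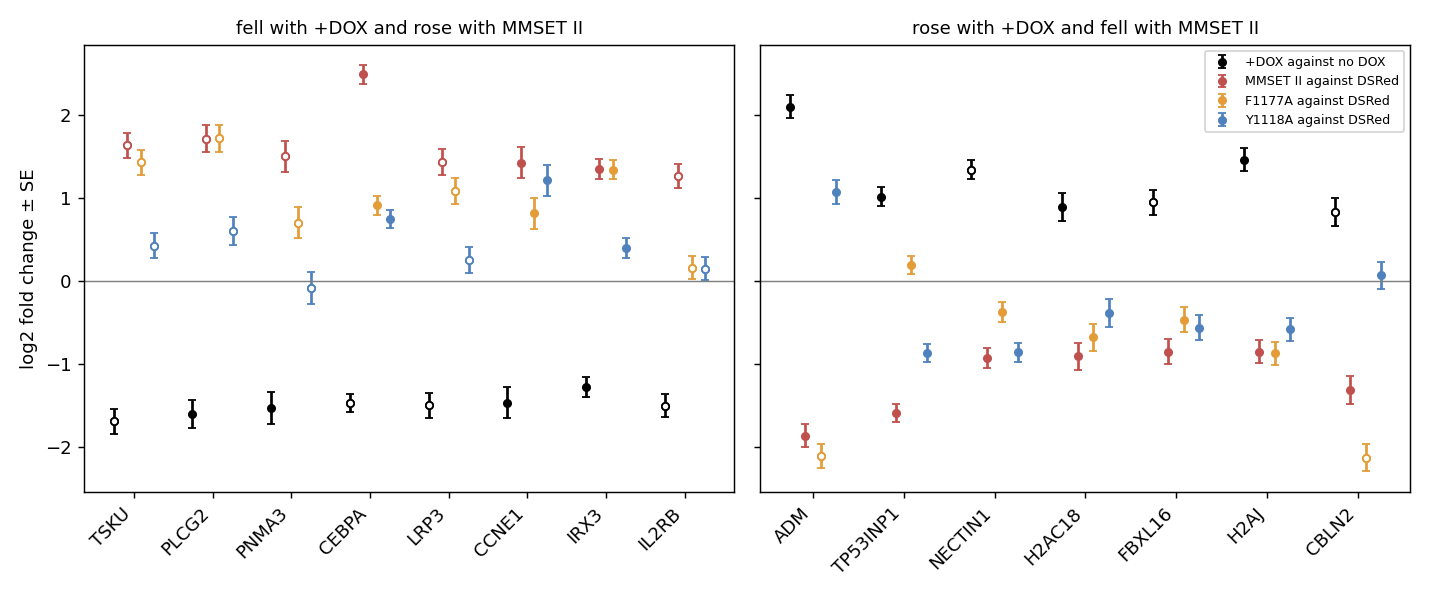
Log2 differences ± SE (3 arrays per group, quantile normalisation) of genes with the largest opposite changes, in knock-down and in each repletion group against DSRed. Open circles have at least 1 of the 2 groups near background, so they do not give the size of a change. CCNE1 lies at -1.46 with +DOX and 1.43 with MMSET II, and ADM at 2.10 and -1.86; under median scaling H2AC18 and FBXL16 are not called with MMSET II.

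As a set, the 2206 features that fell with +DOX had a median of -0.11 in MMSET II against DSRed (camera p = 0.00137, and p = 0.292 with an estimated correlation), and the 2320 that rose had a median of 0.13 (p = 0.000314, and p = 0.308 with an estimated correlation). For every other processing or omitted array the 2 sets were chosen anew from its own +DOX calls, so they hold partly other features. Under median scaling 194 features fell and 4573 rose with +DOX. That scaling moved the median of all features to 0.212, and the set medians were 0.13 and 0.29, or -0.0825 and 0.0774 relative to all features. Without DSRed replicate 3 these medians were -0.20 and 0.20, and the median of the features that rose was 0.08 without DSRed replicate 1. With F1177A the medians lay the other way, at 0.09 for features that fell (p = 9.87e-06, and p = 0.154 with an estimated correlation) and -0.12 for those that rose (p = 3.62e-05, and p = 0.246 with an estimated correlation). With Y1118A they were -0.10 (p = 0.000548, and p = 0.257 with an estimated correlation) and 0.11 (p = 0.000441, and p = 0.32 with an estimated correlation). Counted by gene, 769 features moved oppositely in knock-down and F1177A repletion (463 for independent lists) and 290 the same way (467), and with Y1118A 425 moved oppositely (626) and 941 the same way (629). With no detection filter these counts all lay above independent lists. They were 461 and 153 with F1177A (89.7 and 90.8) and 252 and 509 with Y1118A (116 and 117). The F1177A counts were 1199 and 378 without no DOX replicate 1, 550 and 347 without DSRed replicate 3, 492 and 211 without F1177A replicate 2 and 542 and 183 without F1177A replicate 3. Those of Y1118A were 685 and 1173 without no DOX replicate 1, 324 and 571, 301 and 565 and 480 and 1700 without DSRed replicates 1, 2 and 3, and 300 and 606 without Y1118A replicate 3. Without DSRed replicate 3 the medians were 0.02 and -0.04 with F1177A and -0.18 and 0.19 with Y1118A, and without DSRed replicate 1 those of Y1118A were -0.06 and 0.08. These signs follow brightness, since the +DOX, MMSET II and Y1118A arrays were on average brighter than their controls and the F1177A arrays dimmer. DSRed replicate 3, at 1033, was brighter than any other array, and its estimated array weight was 0.204, against 1.2 and 2.2 for DSRed replicates 1 and 2. Without it the brightness differences from DSRed were 0.676 with MMSET II, -0.202 with F1177A and 0.691 with Y1118A, without DSRed replicate 1 0.14, -0.738 and 0.156, and without DSRed replicate 2 0.0825, -0.796 and 0.0978. With array brightness as a covariate in both comparisons the medians were -0.08 and 0.07 with MMSET II, 0.07 and -0.07 with F1177A and -0.02 and 0.02 with Y1118A. With it 512 features moved oppositely and 890 the same way with MMSET II (588 and 589 for independent lists), 532 and 224 with F1177A (305 and 308) and 502 and 577 with Y1118A (463 and 466). Under median scaling, relative to all features, the medians were 0.438 and -0.0767 with F1177A and -0.197 and 0.0599 with Y1118A. There 700 features moved oppositely and 81 the same way with F1177A (611 and 159) and 46 and 254 with Y1118A (53.9 and 308). Over all features the log2 differences of knock-down correlated at 0.163 with MMSET II, -0.246 with F1177A and 0.208 with Y1118A, across genes, which are not independent.

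The 3 constructs had more calls against DSRed in common than independent lists give, which do not allow for the shared DSRed arrays. MMSET II and Y1118A both raised 955 features (286 for independent lists) and both lowered 790 (214), MMSET II and F1177A 667 (219) and 317 (152), and F1177A and Y1118A 566 (198) and 271 (119). The log2 differences correlated at 0.674, 0.464 and 0.370, against 0.5 for 200 simulations of unchanged groups with shared DSRed arrays. Their covariances were 0.116, 0.0803 and 0.0536, against a simulated 0.012. The simulations gave each feature 1 spread in all groups, which by itself sets the correlation at 0.5. Residual SDs were 0.133 to 0.237 on the DSRed arrays and 0.0812 to 0.0923 on the Y1118A arrays. A noisier shared control raises both simulated values, so the correlations do not show more agreement than shared noise gives. The simulations hold the spread between arrays alone, so a difference of the DSRed culture from the others, which all 3 contrasts share, is not in them, and part of the excess overlap may come from it.

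Lists on other subjects were called in none of the 7 comparisons. These were the MMSET neighbours and relatives (9 measured, adjusted p 0.559 to 0.963), earlier B-cell genes (10, 0.248 to 0.966), p53 targets (14, 0.278 to 0.77), apoptosis (25, 0.213 to 0.931), adhesion (19, 0.141 to 0.95), interferon-stimulated genes (20, 0.226 to 0.891), NF-kB targets (16, 0.213 to 0.886) and immediate early and heat shock genes, which respond to handling (17, 0.0982 to 0.663). Over the 7 comparisons their members were called higher and lower 6 and 2, 20 and 13, 16 and 18, 33 and 31, 30 and 25, 28 and 19, 32 and 18, and 26 and 29 times, and adjusted over the list alone 6 and 2, 21 and 17, 15 and 20, 34 and 32, 31 and 27, 30 and 20, 33 and 20, and 27 and 32 times. Lists of cancer-testis genes (2 measured), myeloid markers (3), T and NK cell markers (3) and erythroid markers (2) had too few measured members to test.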

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

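The test of the shared DSRed arrays was chosen after its result had been seen, and the array brightness adjustment was added after the data had been examined. Differences between constructs under the same contrast with DSRed drew attention here. MMSET II and Y1118A moved 42 genes in opposite directions against DSRed, MMSET II and F1177A 197, and F1177A and Y1118A 87, where independent lists give 496, 367 and 307. All 3 counts lie under those numbers. The contrasts share the DSRed arrays, which alone gave a correlation of 0.5 in simulations of unchanged groups with equal spread. A count under that of independent lists thus follows from the design, and no conclusion is drawn from it. The difference between the constructs was also called for each gene moved oppositely, which choosing genes by opposite calls against the same DSRed arrays makes nearly certain.

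For each comparison the 6 arrays can be split in 10 ways, which is too few for a share under 0.05. In every comparison 1 split, the real one, gave as many called genes. The real count and the highest of the other splits were 4526 and 22 for +DOX against no DOX, 3594 and 378 for MMSET II against DSRed, 2250 and 0 for F1177A against DSRed, 3038 and 0 for Y1118A against DSRed, 2025 and 0 for MMSET II against Y1118A, 4251 and 0 for F1177A against MMSET II, and 4020 and 0 for F1177A against Y1118A. For the genes that moved oppositely in knock-down and MMSET II repletion, 2 of 100 drawn splits gave as many as the real 539, but the splits seen in each comparison above call few genes and could hardly reach it, and 539 lies under the 742 of independent lists, although 351 with no detection filter and 150 at 1.5-fold lie over their 152 and 138. Whether opposite genes exceed independent lists thus depends on the setting, partly through the number of features tested, and chance is not excluded for them. The highest other split, 1138, is the real one with the labels of 1 system exchanged, so it counts the genes that moved the same way.

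Many genes were called where the groups also differed in array brightness. After adjustment for brightness, with its slope estimated within groups, the log2 differences of the called genes kept a slope on the unadjusted ones of 0.84 for +DOX against no DOX (0.792 to 0.888 without each array in turn), 0.754 for F1177A against MMSET II (0.709 to 0.798) and 0.664 for F1177A against Y1118A (0.61 to 0.696). This argues against brightness as the whole cause of these calls. A partial share stays open, as the slopes lie under 1. The counts fell to 3201, 2537 and 1319, but a covariate that differs between groups also widens the errors, which alone lowers counts. An effect of doxycycline apart from the hairpin stays open too, because no array received doxycycline without it, as does a biological effect of MMSET.

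More genes moved the same way than oppositely in knock-down and MMSET II repletion, by more than independent lists give except under median scaling (498 and 105, against 515 and 113), although the labels describe MMSET as lowered in one and restored in the other, which the NSD2 probe did not show for the repletion. The brighter group was the +DOX and the MMSET II group. Brightness may contribute: the share of the covariance left after adjustment was 0.639, but it ranged from -0.568 to 1.08 without single arrays, so this stays open. A response to doxycycline or to infection, and a biological one, were not tested.

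Y1118A, labelled inactive, had many calls against DSRed in common with MMSET II. Of the covariance of their log2 differences, brightness accounted for 0.0632 (0.00689 to 0.256 without each array in turn), which argues against it as the whole cause. The shared DSRed arrays may be a cause, through noise or a difference of that culture. With F1177A in place of DSRed on the MMSET II side, which takes off what DSRed adds, and without the part from brightness, a share of 0.352 was left. It was 0.187 without DSRed replicate 3 and up to 0.418 without other arrays, and 0.25 was the limit for excluding this explanation, so it stays open. The exchange also takes off any response that all 3 constructs have in common. A low share could thus not tell such a response from an effect of DSRed. An effect of MMSET protein that does not need its catalytic activity, or of infection with a larger insert, may remain, and neither was tested.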

How the results depend on the processing

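Array brightness as a covariate was the alternative added after the data had been seen for the values below, with a paired fit for F1177A against MMSET II, which called 6105 features. Counts are in the order +DOX against no DOX, MMSET II, F1177A and Y1118A against DSRed, MMSET II against Y1118A, F1177A against MMSET II and F1177A against Y1118A, with 4526, 3594, 2250, 3038, 2025, 4251 and 4020 features called. An adjusted p of 0.01 gave 2962, 2284, 1159, 1687, 1141, 2681 and 2232, and a minimum of 1.5-fold gave 1995, 1519, 925, 1127, 796, 1740 and 1569, as stricter thresholds call fewer features. Detection on all 18 arrays, which tests fewer features, gave 1441 for F1177A against DSRed.

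Median scaling gave 1443 for MMSET II against DSRed, 831 for Y1118A against DSRed, 561 for MMSET II against Y1118A, 6543 for F1177A against MMSET II and 6831 for F1177A against Y1118A. Array weights gave 6119, 3529, 6405, 4497 and 6374 for MMSET II, F1177A and Y1118A against DSRed, MMSET II against Y1118A and F1177A against Y1118A. A model of the compared groups alone gave 2828 with +DOX, 4074 for MMSET II against Y1118A and 6123 for F1177A against Y1118A, and brightness as a covariate 2537 for F1177A against MMSET II and 1319 for F1177A against Y1118A. Residual SDs were 0.186 to 0.284 on the no DOX arrays and 0.0812 to 0.0923 on the Y1118A arrays. The main model takes 1 variance per feature for all groups. Its p-values may thus be too small with +DOX and too large for MMSET II against Y1118A. How much each cause adds to these counts was not tested. Other alternatives, apart from single arrays, moved these counts by less than 1.5 times.

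Leaving out single arrays gave 3599 to 5097, 2648 to 4388, 1506 to 2083, 1901 to 4272, 1348 to 1526, 2998 to 3790 and 2740 to 3443 features. Moves over 1.5 times came without DSRed replicate 1 (1901), DSRed replicate 2 (1923) or Y1118A replicate 3 (2016) for Y1118A against DSRed and without Y1118A replicate 1 (1348) for MMSET II against Y1118A. The 539 opposite and 1138 same-way genes (742 and 743 for independent lists) became 105 and 498 (113 and 515) with median scaling, 351 and 703 (152 and 153) with no detection filter, 319 and 659 (417 and 417) with the compared groups alone, 273 and 553 (308 and 309) at an adjusted p of 0.01, 150 and 299 (138 and 138) at 1.5-fold, and 773 and 1994 (1280 and 1280) with array weights. Without single arrays they were 421 to 799 and 775 to 1773, the last without DSRed replicate 3. Features that fell or rose with +DOX were chosen anew for each processing and omitted array, 194 and 4573 of them under median scaling. The median of features that fell with +DOX was 0.129 in MMSET II against DSRed with median scaling (p = 0.478), or -0.0825 relative to all features, and was -0.113 with p = 0.292 with an estimated correlation. It was -0.195 to -0.0765 without single arrays. For features that rose it was 0.125 with p = 0.308 with an estimated correlation, and 0.082 to 0.203 without single arrays. The extremes were without DSRed replicate 3 (-0.195 and 0.203) and, for features that rose, without DSRed replicate 1 (0.082). The cause was not tested.

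Median scaling moved the median of all features to 0.486 with +DOX, -0.413 for F1177A against DSRed, -0.62 for F1177A against MMSET II and -0.618 for F1177A against Y1118A. With it FGFR3 turned to 0.0087 with +DOX, -0.081 for F1177A against DSRed and -0.012 for F1177A against MMSET II, TACC3 to -0.75 and SLBP to -0.64 for F1177A against Y1118A, KIF20A to -0.023, CENPE to -0.048, PSMB8 to -0.067, EZH2 to -0.0076 and CBX7 to -0.11 for F1177A against DSRed, and TAP1 to -0.068 for F1177A against MMSET II. Relative to those medians only TACC3 (-0.129) and SLBP (-0.0209) turned among these. Median scaling sets each array by the median over all 48803 probes, most of them not detected, which leaves brightness in the tested features. The shifts of the medians above have the signs of the brightness differences, 0.752, -0.579, -0.878 and -0.894 in the same order. The other CCL3L1 probe gave -0.014 for MMSET II against Y1118A, and the cause of this was not tested. Of 340 called results of named genes, 129 lost the call or turned under some alternative. Replicate numbers as a block gave 4400, 3434, 2108, 2883, 1869, 4090 and 3827 features. All 6 arrays matched their own number best only for F1177A against MMSET II, and 5 of 6 did so for Y1118A against DSRed. For F1177A against MMSET II the block changed no call of a named gene or list. Slide as a block was not run, as the files give no slide. Signal over background limits dim genes, whose changes the offset understates.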

Other observations

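The set of genes shared by both active constructs was chosen after the results were seen. Genes that fell with +DOX and rose with F1177A (435) might depend on catalytic activity and then be higher with MMSET II than with Y1118A, arrays that took no part in choosing them. Their median there was 0.061, with 92 called higher and 60 lower (camera p = 0.00777, and p = 0.325 with an estimated correlation), so the question stays open. With array brightness as a covariate it was 0.0565 (p = 0.166 with an estimated correlation), though the genes themselves were chosen without it, from +DOX arrays brighter than their controls by 0.752 and F1177A arrays whose brightness difference was -0.579. The 334 genes that rose with +DOX and fell with F1177A had a median of 0.0485 there, on the other side of 0 from the prediction, and 0.0524 with brightness as a covariate.

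Both MMSET II and F1177A were higher than both DSRed and Y1118A for 211 features, of which 73 fell with +DOX (42.5 for independent lists), 26 rose (44.7) and 112 were not called. With median scaling these counts were 17 and 24, where over all features 194 were called lower with +DOX and 4573 higher. Numbers for independent lists were not computed there, so the order of 17 and 24 alone shows no reversal. Without no DOX replicate 1 they were 82 and 40. Log2 differences with +DOX, MMSET II, F1177A and Y1118A, the last 3 against DSRed, were -1.11, 4.08, 3.67 and 1.84 for S100A10, -1.23, 2.24, 2.17 and 1.11 for EVL, and -1.22, 1.90, 2.55 and 0.89 for MTURN. Both were lower for 63 features, of which 16 rose with +DOX (13.3) and 7 fell (12.7). These counts were 32 and 12 without no DOX replicate 1, 8 and 6 without MMSET II replicate 2, 10 and 4 without Y1118A replicate 2 and 9 and 3 without Y1118A replicate 3, 14 and 13 with cyclic loess, 7 and 0 with median scaling, and 2 and 2 at an adjusted p of 0.01, so they carry no conclusion.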
